A study of Mus musculus with 30 samples.

How the data were processed

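The series holds SCAR-seq and OK-seq libraries of E14TG2a mouse embryonic stem cells, wild type or carrying the MCM2-2A changes in the histone-binding part of MCM2. Of 30 samples in 17 groups, 1 had a processed file, the wild-type OK-seq library labelled with 10 µM EdU for 2 min. The other 29 samples were not analysed here, and with 1 library there was no comparison between groups and no replicate error. The extraction text in the labels is the same for all samples and describes nucleosome immunoprecipitation and capture of EdU-labelled DNA, and how Okazaki fragments were isolated is not given in the sources used here.

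Per the submitters' processing notes, the tools were BWA 0.7.13, bcl2fastq, Trim Galore 0.4.2, Bowtie, Picard 2.8.2 and SAMtools, and the build was mm10; their roles and settings are not given in the sources used here. The deposited list holds distances in bp and no counts, scores or signal. Per the file headers, each entry is a breakpoint bin with a minimum on its left, a maximum on its right, the distances to both, their difference as the size, and the distance to the nearest other breakpoint. The quantity whose minimum and maximum were taken, its smoothing and the calling thresholds are not given in the sources used here. In all 2844 entries the size matched the difference of the distances, and the nearest distance matched one recomputed from the bins. No arm exceeded 100 kb, so widths stop at 200 kb and long zones may be shortened. Width is the distance between the bins at the edges, so an interval spans 1 kb more than its width. All entries lay on chromosomes 1 to 19; chromosomes X and Y were not analysed here. The depth of the library is unknown, so no value could be weighted by it.

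Gene positions came from an NCBI RefSeq gene table of GRCm38.p6, the same build as mm10. It gave symbols, starts and ends without strand, and no genome sequence was used. Genes placed on scaffolds (333) were left out, which left 20558 protein-coding genes and 46709 genes of all kinds. The design fixed before the data were examined asked for transcription start sites; since strand was not used, either end of a gene took their place throughout. For the same reason the orientation of flanking genes, GC content, strand composition and chromosome length without gaps were not analysed here. The span of a chromosome ran from the first to the last base of an annotated gene or zone. Genes that start before 3 Mb, or that follow the first drop in start position in the table, were taken as lying on scaffolds.

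Zone density was the number of zones per Mb of span with an exact Poisson interval (95%). Neighbour distances were set beside 1000 independent random placements of the same number of breakpoints on each chromosome. The share of zones with a gene end inside (Wilson 95% interval), the share of zone bases in gene bodies and the share of breakpoints in gene bodies were set beside 1000 rotations, in which all zones of a chromosome moved by a common random offset. Gene lists were described by the share of genes with an end within 20 kb of a zone and set beside 10000 random lists of protein-coding genes of the same size. The central 95% of placements or lists is given as their range, and no p-value was computed across zones or genes. The correlation of zone and gene density across chromosomes used 100000 permutations, two-sided; it, the windows of 1 Mb, the profile around breakpoints and the counts of short distances were added after the data were seen.

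The 15 gene lists were fixed before the data were examined: pluripotency, DNA replication, histone chaperones, enzymes of H4K20, H3K36 and H4K5, cell cycle, neural lineage, mesoderm and endoderm lineage, imprinted, very long, ribosomal protein, histone (core and linker, matched by symbol), Hox, olfactory receptor, vomeronasal receptor and Zfp zinc finger genes. In each list up to 4 genes inside a zone with an end nearest to its breakpoint and the 1 gene farthest from any zone were named, with up to 3 genes in each of the 5 widest zones and Mcm2. Some genes that this rule picks are not reported here. A few further genes were named after their values were seen, as stated beside them.

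Alternatives fixed beforehand were merging of zones less than 10 kb apart, only zones at least as wide as the median, other denominators and covered share for density, gaps in place of breakpoint distances, gene ends within 10 kb of the zone or in its central part, genes of all kinds, independent placement in place of rotation, the breakpoint in place of zone bases, limits of 5 and 50 kb for lists, random lists matched on gene number within 250 kb or built from runs of neighbours, and other forms of the relations across zones. Added after the data were seen were placements of breakpoints within their own 5 Mb window, the point midway between the edges, gene midpoints, lists matched on gene length in 10 classes, zones below the 100 kb limit, overlapping zones joined, and the breakpoint with other zones or genes.

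Simulated data over the 20558 genes, in 40 runs each, tested the gene-end share, gene-body bases, gene list share and spacing. The share of breakpoints in gene bodies was not tested in this way. With no effect simulated, the share of zones with a gene end fell outside the range in 2 runs, the gene list share in 0, spacing in 1 and gene-body bases in 2. With 10% of zones moved to gene ends, the gene-end share lay above the range in 40 of 40 runs and gene-body bases in 16 of 40. No zones were moved into gene bodies, so recovery of an excess planted there was not tested. Planted gene lists and planted even spacing were recovered in 40 of 40. Every planted list held the same large share of near genes, so recovery of a weaker excess was not tested. Against placements within 5 Mb windows, spacing fell outside the range in 2 of 40 runs with no effect and below it in 40 of 40 without pairs closer than 150 kb. In the same settings, the variation of distances beyond 200 kb fell outside the range in 1 of 40 runs and above it in 40 of 40, and it was below the range in 40 of 40 runs with even spacing. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.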

Results

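The series asked how old and new histones are shared between the daughter DNA strands when the replication fork passes, and what the histone-binding part of the replicative helicase subunit MCM2 contributes. Its 30 samples come from E14TG2a, an established mouse embryonic stem cell line grown with LIF and inhibitors of GSK3 and MEK, and they fall into 17 groups. SCAR-seq, which sequences the newly made strand of EdU-labelled nucleosomal DNA, covered H4K20me2, H3K36me3, H4K5ac and inputs in wild-type cells and in clones 1 and 2 of the histone-binding mutant MCM2-2A. The 29 SCAR-seq samples were not analysed here, so no mutant was compared with wild type. The 1 sample analysed was a wild-type OK-seq library, made after 2 min of labelling with 10 µM EdU. OK-seq sequences Okazaki fragments by strand, and thereby shows in which direction forks travel and where leftward and rightward forks part. These places are the initiation zones of replication, and their list is the measurement described here. The depth of the library is unknown, because the list carries no read counts, and a single library gives no replicate error.

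The list held 2844 initiation zones on chromosomes 1 to 19 (mm10), each with a breakpoint bin of 1 kb, a left edge and a right edge. The median zone was 112 kb wide (95% order-statistic interval 110 to 113 kb), with quartiles of 82 and 138 kb and a range of 36 to 200 kb. Zones covered 311.7 Mb, or 12.98% of the 2402 Mb searched. The left arm of a zone had a median of 51 kb and the right arm of 52 kb. Both arms stopped at 100 kb, a limit that 272 zones (9.56%) reached on at least 1 side. Arms over 95 kb, those at the limit included, numbered 329 on the left and 318 on the right. Among neighbouring zones, 88 pairs overlapped, and 62 of these shared both edges, so that the same interval was listed with 2 breakpoints; joining overlaps left 2756 intervals.

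The 5 widest zones, at 200 kb, lay in surroundings that differed in gene content; 7 zones tied at this width and were taken in genome order. On chromosome 2, the zone from 130559001 to 130760000 held an end of 10 protein-coding genes. Its central genes were Ddrgk1, Itpa, which encodes the enzyme that removes inosine triphosphate, and Lzts3. A second zone of chromosome 2, from 164760001 to 164961000, held an end of 15 genes, among them the phospholipid transfer protein gene Pltp, Pcif1 and the cathepsin A gene Ctsa. The chromosome 6 zone from 119365001 to 119566000 held an end of 4 genes, including Wnt5b, a Wnt ligand, the adiponectin receptor gene Adipor2 and Fbxl14. The other 2 of these 5 zones, both on chromosome 5, held an end of a single gene each. The Mediator subunit gene Med13l reached into the zone from 118363001 to 118564000, and Adgra3 into the zone from 50016001 to 50217000.

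Zones were densest on chromosomes 19 and 11 and sparsest on chromosome 14. Chromosome 19 held 1.56 zones per Mb (exact Poisson 95% interval 1.26 to 1.92) and chromosome 11 held 1.49 (1.28 to 1.73), against 0.912 (0.751 to 1.10) on chromosome 14 and 1.18 (1.14 to 1.23) over all 19 chromosomes. The gene-rich chromosomes tended to carry more zones. Across the 19 chromosomes, zones per Mb and protein-coding genes per Mb correlated with Pearson's r = 0.668 (permutation p = 0.002, two-sided) and Spearman's rho = 0.649 (permutation p = 0.003). Without chromosomes 7 and 11, whose gene density lay farthest from the median, r was 0.749 (permutation p = 0.0004) and rho 0.690 (permutation p = 0.003) over 17 chromosomes. This was the only relation computed across chromosomes, and its p-values were not adjusted. Since it was added after the data were seen, they are descriptive only. Chromosome 7, the most gene-rich at 14.2 genes per Mb, held 1.17 zones per Mb, a value near that of all chromosomes. In windows of 1 Mb, pooled over all chromosomes, zones were also denser where genes were. The 269 windows without a protein-coding gene held 0.595 zones per Mb (0.506 to 0.694), and 54.7% of them had no zone. Windows with 1 to 4 genes held 0.806, those with 5 to 9 genes 1.29, and those with 10 to 19 genes 1.64. The 266 windows with 20 or more genes held 1.84 zones per Mb (1.68 to 2.01), and 13.2% of them had no zone. The Poisson intervals cover counting error only.

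**Figure D1:**
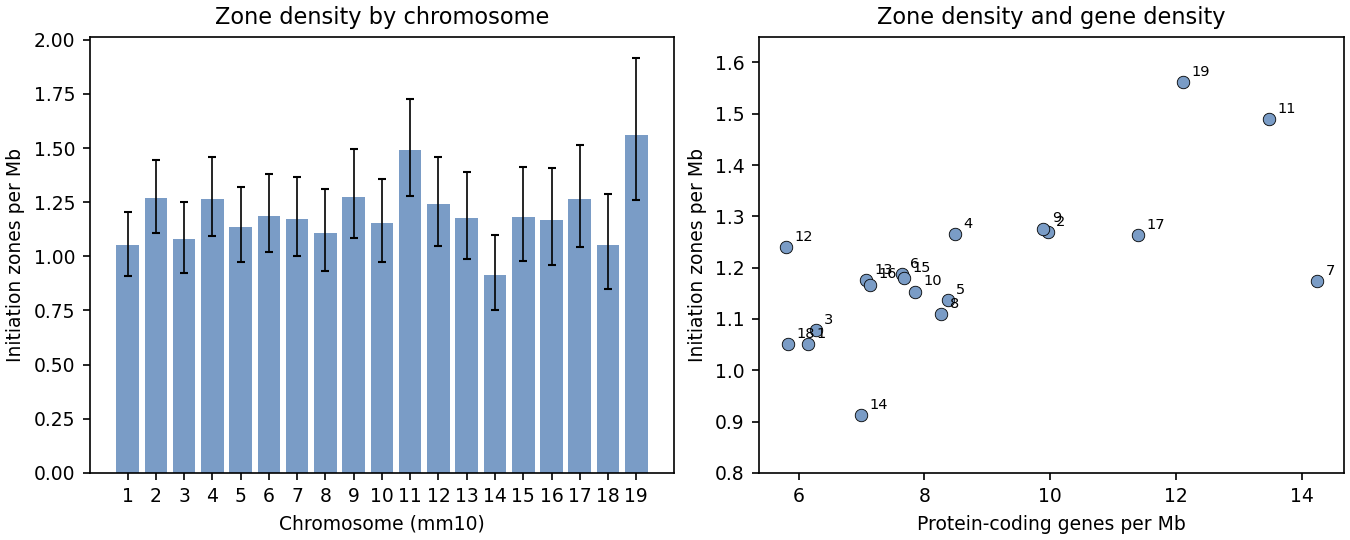
Left, initiation zones per Mb on each of the 19 chromosomes (mm10), with bars for the counts and error bars for exact Poisson 95% intervals; right, the same densities against protein-coding genes per Mb, with 1 numbered point per chromosome. Chromosomes 19 (1.56 zones per Mb) and 11 (1.49) stand highest and chromosome 14 (0.912) lowest, and chromosome 7 lies below the trend of the others at 14.2 genes per Mb.

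Breakpoints were spaced somewhat more evenly along chromosomes than independent placement gives. The median distance between neighbouring breakpoints was 592 kb, within the range of 1000 independent placements on the same chromosomes (mean 579.7 kb, central 95% of placements 557.4 to 602 kb). The coefficient of variation of the distances was 0.930, below the placements (mean 1.00, 0.969 to 1.04), and 0 of the 1000 placements gave a value as low. Short distances were scarce. There were 76 neighbours within 50 kb, against 164.9 in the placements (143 to 187), and 386 within 200 kb, against 602 (564 to 639). With zones less than 10 kb apart merged, the coefficient of variation was 0.893, within the placements (0.836 to 0.906), and the median distance of 622 kb lay below them (689.4 to 739.9 kb).

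Most initiation zones held the end of a protein-coding gene. An end of at least 1 gene lay inside 2395 of the 2844 zones (84.2%, Wilson 95% interval 82.8 to 85.5%). When all zones of a chromosome were rotated together by a random offset, 52.6% of zones held a gene end (1000 rotations, of which the central 95% lay at 50.8 to 54.4%), and no rotation exceeded 55.7%. The listed share was 1.60 times the rotated one. Either end of a gene was counted, since strand was not used here, so starts and stops of transcription were not separated.

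Gene bodies were arranged around breakpoints in a regular way, low at the centre and high at the flanks. The breakpoint bin itself lay in a protein-coding gene body in 830 zones (29.2%, 27.5 to 30.9%), against 41.1% in the rotations (39.4 to 43.1%). Gene-body cover then rose to 58.7% at 50 kb left of the breakpoint and to 60.3% at 60 kb right of it, with rotations at 41.2% at both places. It was still 47.6% at 300 kb left and 47.3% at 300 kb right. Over whole zones, 45.8% of bases lay in gene bodies, against 41.2% (39.8 to 42.6%) in the rotations, so the share of zone bases lay above the rotations while the share of breakpoints lay below them. Gene ends were most frequent on the shoulders, at 0.368 per 10 kb at 20 kb left and 0.379 at 20 kb right, with 0.331 at the breakpoint and 0.175 in the rotations. The intervals of these shares treat zones as independent and cover counting error only.

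**Figure D2:**
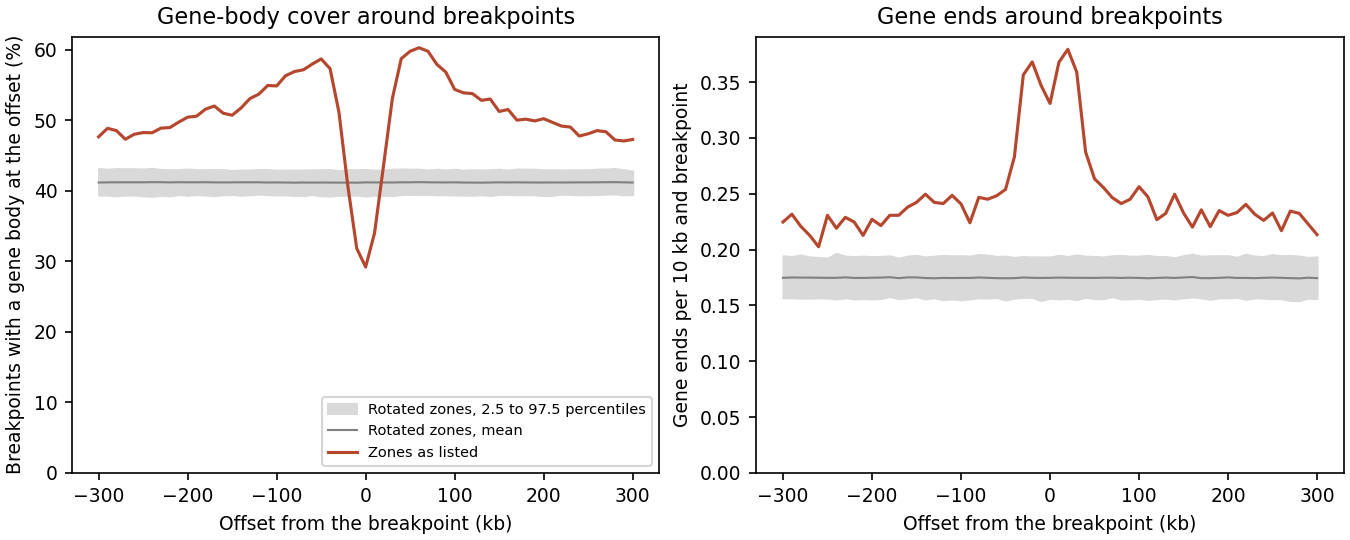
Left, share of the 2844 breakpoints with a protein-coding gene body at each offset from 300 kb left to 300 kb right (steps of 10 kb); right, gene ends per 10 kb and breakpoint at the same offsets, with the red line for zones as listed, the grey line for the mean of 1000 rotations and the grey band for their central 95%. Gene-body cover falls to 29.2% at the breakpoint between shoulders of 58.7% and 60.3%, and gene ends peak at 0.368 and 0.379 per 10 kb at 20 kb on the left and right.

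Genes of ribosomal proteins, histone chaperones, the cell cycle and histone-modifying enzymes lay near initiation zones more often than random genes, and chemosensory receptor, Hox and histone genes less often. The calls for Hox and histone genes were lost when random lists kept runs of neighbouring genes. Of all 20558 protein-coding genes, 6664 (32.4%) had an end inside a zone and 7921 (38.5%) within 20 kb of one. Of the 15 gene lists fixed beforehand, 4 lay above and 4 below the central 95% of 10000 random lists of the same size, where chance would place 0.75 lists outside. Lists could share genes. Hat1, with an end inside a zone, counted in both the chaperone and the histone enzyme list, so their calls are not independent. These ranges describe the 1 library, and no p-value was computed across genes.

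Ribosomal protein genes showed the clearest nearness for a large list, with 51 of 80 (63.8%) within 20 kb of a zone, against 27.5 to 48.8% for random lists. In Rps14 (chromosome 18, 60774596 to 60778546), Rps16 and Rpl34 the nearer gene end lay 0.096, 0.198 and 0.327 kb from the breakpoint. Here and below, distances to a breakpoint run to the middle of its bin of 1 kb. Values well below 1 kb therefore do not rank genes. Histone chaperones, which carry histones to and from DNA, had 16 of 21 genes (76.2%) within 20 kb, against 19.1 to 61.9%. Hjurp, the chaperone of the centromeric histone CENP-A, had an end 0.144 kb from a breakpoint. Npm1, the transcription elongation factor gene Supt6 and Hat1, whose product acetylates new histone H4, followed at 14.4, 19.3 and 20.8 kb, and Asf1a was the farthest from any zone, with 877.8 kb to the nearest zone edge. Cell cycle genes had 21 of 33 (63.6%) within 20 kb, against 21.2 to 54.6%. The nearest were the CDK inhibitor gene Cdkn2a (0.973 kb), the phosphatase gene Cdc25b (1.99 kb), Cdk2 (4.45 kb) and Dbf4 (8.53 kb), the activator of Cdc7 kinase. Cdc7 itself was the farthest from any zone, with 1021 kb to the nearest zone edge. Among enzymes of H4K20, H3K36 and H4K5, 14 of 22 (63.6%) lay within 20 kb, against 18.2 to 59.1%. The demethylase genes Kdm4c (3.997 kb) and Kdm2a (13.8 kb), the H4K20 methyltransferase gene Kmt5b (15.2 kb) and the acetyltransferase gene Kat7 (17.3 kb) were nearest, and Kmt5c, a second H4K20 methyltransferase gene, lay 1030 kb from the nearest zone edge. The excess of these enzymes over random lists of 25.1 percentage points turned to -0.709 with only zones at least as wide as the median and to -2.56 with gene midpoints, and their list also returned to the random range at 5 kb, at 50 kb and with random lists matched on gene length. With the wide zones, the excess of chaperones (19.4 points, from 37.6) and of ribosomal proteins (9.10, from 25.3) also fell within the random range.

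Pluripotency and DNA replication genes lay at the upper bound of the random range without passing it. Of 23 pluripotency genes, 13 (56.5%) were within 20 kb of a zone, against 21.7 to 56.5%. Fgf4 (chromosome 7, 144861386 to 144865245), Zfp42, Tdgf1 and Klf5 had ends 1.11, 1.51, 2.66 and 4.81 kb from a breakpoint, and each held a breakpoint in its body, while Sall4 lay 554.3 kb from the nearest zone. The core factors Pou5f1, Sox2 and Nanog, named after their values were seen, all had an end inside a zone, at 6.72, 73.0 and 4.87 kb from its breakpoint, whereas Klf4 was 137.1 kb from a zone. Of 39 DNA replication genes, 21 (53.85%) were near, against 23.1 to 53.85%. Rfc2 and Rfc5, which encode subunits of the clamp loader, Orc2, of the origin recognition complex, and Mcm4, of the MCM helicase, had ends 3.17, 4.36, 4.39 and 5.40 kb from a breakpoint, and the DNA ligase gene Lig1 was farthest, at 1281 kb from a zone. Among the other MCM helicase genes, named after their values were seen, Mcm5, Mcm6 and Mcm7 had ends inside zones and Mcm3 lay 384.7 kb from one. The pluripotency list passed the random range with wide zones (47.8%, against 8.70 to 43.5%) and with gene midpoints, and the replication list at 5 kb (53.8%, against 20.5 to 48.7%) and with gene midpoints.

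Lineage, imprinted, very long and Zfp zinc finger genes did not stand apart from random lists. Neural lineage genes had 9 of 19 within 20 kb (47.4%, against 15.8 to 63.2%). The neurogenic factor gene Neurod1 and the eye field regulator Pax6 had ends 0.137 and 8.60 kb from a breakpoint and Slc17a7 42.4 kb. Mesoderm and endoderm genes had 7 of 20 near (35.0%, against 20 to 60%), with Eomes, Foxa2, Gata6 and Gsc at 1.31, 1.38, 3.01 and 6.26 kb from a breakpoint and Myod1 416.9 kb from a zone. Of 17 imprinted genes, 7 were near (41.2%, against 17.6 to 64.7%). Phlda2, Impact, Grb10 and Snrpn had ends 18.4, 19.2, 24.0 and 40.01 kb from a breakpoint, and Ube3a lay 538.8 kb from a zone. Very long genes had 5 of 19 near (26.3%, against 15.8 to 63.2%). Csmd3, which spans 1212 kb, Auts2, Immp2l and Wwox had an end 18.9, 21.3, 31.6 and 33.1 kb from a breakpoint, and Dpp10 lay 327.1 kb from a zone. With gene midpoints none of the very long genes (0%) lay within 20 kb of a zone, against 10.5 to 52.6% of random lists. Of 386 Zfp genes, 134 (34.7%) were near, against 33.7 to 43.5%. Zfp462, Zfp945, Zfp113 and Zfp408 had ends within 0.256 kb of a breakpoint, and Zfp551 was 2169 kb from a zone. The Zfp list fell below the random range at 50 kb (40.2%, against 40.4 to 50.3%) and with lists matched on gene length (36.01 to 45.6%).

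Among the 15 lists, receptor genes of smell and pheromone sensing had the lowest shares near zones. Of 1099 olfactory receptor genes, 76 (6.92%) lay within 20 kb, against 35.8 to 41.3%, and the median gene was 323.7 kb from a zone, against 71.2 kb in random lists. Of 349 vomeronasal receptor genes, 16 (4.58%) were near, against 33.5 to 43.5%, with a median of 474.6 kb. Exceptions with an end close to a breakpoint were Olfr820 (0.137 kb), Olfr1245 (4.21 kb), Olfr147 (8.67 kb) and Olfr855 (10.0 kb), and Vmn2r3 (3.54 kb), Vmn1r242 (5.67 kb), Vmn1r167 (10.1 kb) and Vmn2r70 (14.2 kb). Olfr1039 was 1273 kb and Vmn1r67 was 4123 kb from the nearest zone. With random lists matched on gene length, the differences shrank from -31.6 to -10.2 percentage points for olfactory genes (range 15.4 to 18.9%) and from -34.0 to -20.3 points for vomeronasal genes (20.9 to 29.2%), both still below the range. These matched lists were drawn from all protein-coding genes, the receptor genes included. Receptor genes were thus partly compared with themselves, so the shrinkage does not measure what gene length contributes. Both families hold near-identical copies on which short reads may not align uniquely, and how such reads were treated is not given in the sources used here.

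Hox and histone genes were also less often near zones than single random genes. Of 39 Hox genes, 8 (20.5%) were within 20 kb, against 23.1 to 53.9%, and all 8 belonged to the Hoxd cluster on chromosome 2, where Hoxd11, Hoxd10, Hoxd9 and Hoxd12 had ends 2.48, 5.23, 8.26 and 11.8 kb from a breakpoint. The nearest genes of the Hoxa, Hoxb and Hoxc clusters were 50.4, 73.3 and 140.1 kb from a zone, and Hoxc13 was farthest, at 248.2 kb. Of 68 core and linker histone genes, most of them in clusters, 13 (19.1%) were near, against 26.5 to 50.0%. The linker histone gene H1f0, outside the large clusters, had an end 27.0 kb from a breakpoint, H4c8, H2ac10 and H3c8 lay in a single zone of chromosome 13 at 63.5, 66.4 and 67.9 kb, and H4f16 was 226.0 kb from a zone. Since members of such clusters share their surroundings, random lists made of runs of neighbours gave wider ranges, which held both the Hox (10.3 to 66.7%) and the histone value (17.6 to 60.3%). Hox genes also returned to the random range at 5 kb, with gene midpoints and with lists matched on gene length, and histone genes at 50 kb, with wide zones, with gene midpoints and with matched lists, where their difference turned to 2.77 points. The mean of these matched lists was 16.35%, against 38.6% for unmatched lists, and their pool held the olfactory and vomeronasal receptor genes. The turn therefore says little about histone genes themselves.

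**Figure D3:**
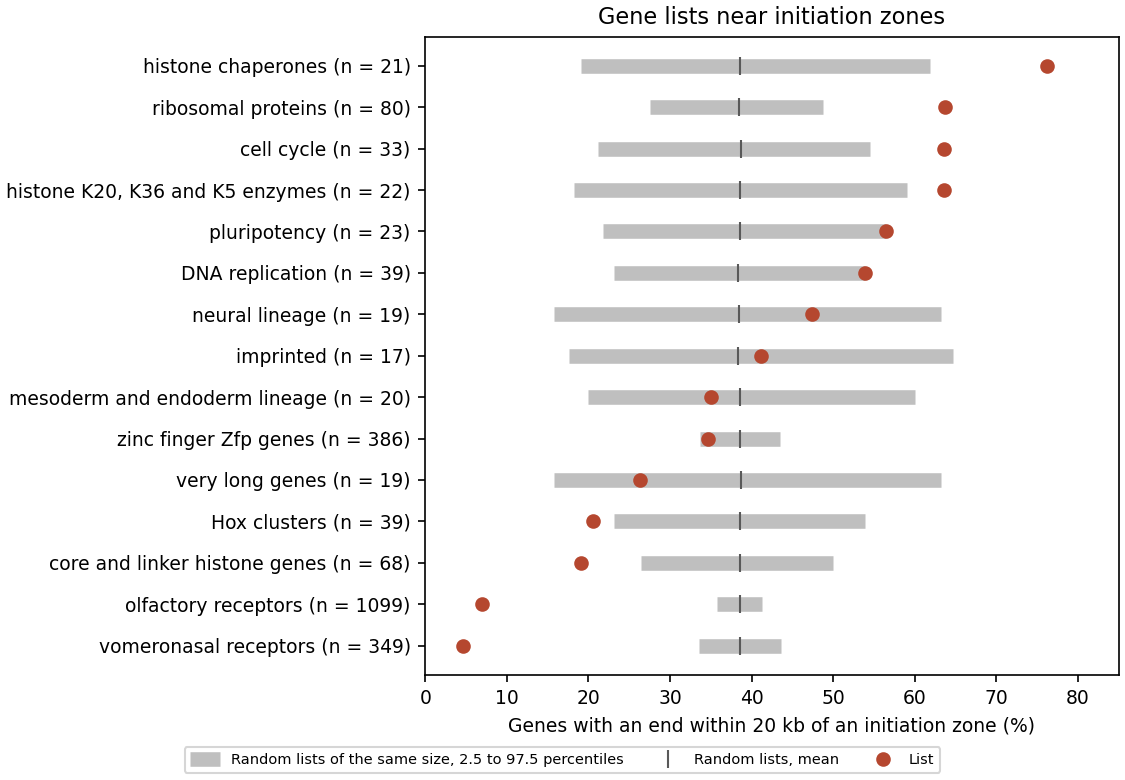
Percent of genes with an end within 20 kb of an initiation zone for the 15 gene lists, with a red point for each list, a grey bar for the central 95% of 10000 random lists of the same size and a tick for their mean. Histone chaperones (76.2%), ribosomal proteins (63.8%), cell cycle genes (63.6%) and histone enzymes (63.6%) lie right of their bars, and Hox (20.5%), histone (19.1%), olfactory (6.92%) and vomeronasal genes (4.58%) left of theirs.

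Mcm2, the gene changed in the mutant clones of the series, lay wholly inside an initiation zone in the wild-type cells. The gene spans 88883474 to 88898780 of chromosome 6, and the zone runs from 88823001 to 88935000. The zone was 111 kb wide and its breakpoint bin, 88869001 to 88870000, lay in the neighbouring gene Podxl2, 14.0 kb from the nearer end of Mcm2. Of 5 protein-coding genes with an end in this zone, the others were Abtb1, Tpra1 and Mgll, whose body reached in from the left.

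**Figure D4:**
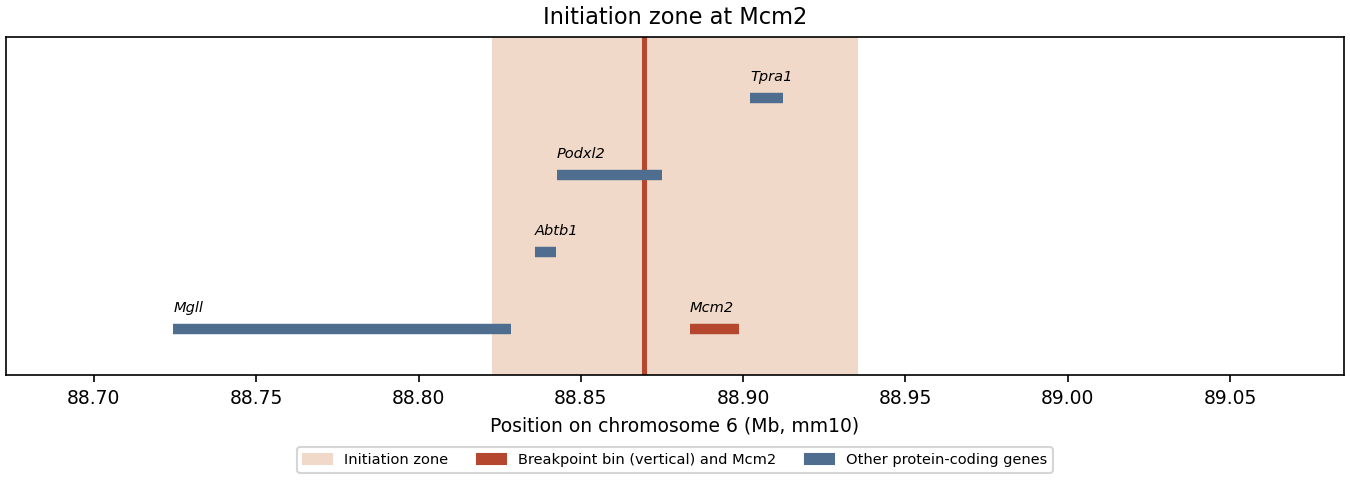
Map of the initiation zone at Mcm2 on chromosome 6 (position in Mb, mm10), with the zone shaded, the breakpoint bin as a vertical red line, Mcm2 as a red bar and the other protein-coding genes as blue bars, at heights that carry no value. The zone of 111 kb holds Mcm2 whole, and the breakpoint falls in Podxl2.

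Zones with genes around them were wider and lay closer to their neighbours. The median width was 89 kb (order-statistic 95% interval 85 to 96 kb) for the 359 zones with no gene end within 100 kb of the breakpoint, and 122 kb (117 to 125 kb) for the 710 zones with 6 to 10 ends; it was 115 kb (108 to 120 kb) for the 455 zones with over 10 ends. The median distance to the nearest other breakpoint was 584 kb without gene ends and 270 kb with over 10 of them. Across the 2844 zones, Spearman's rho of width with gene ends was 0.135 (SD over chromosomes 0.0898, positive on 17 of 19), and that of nearest distance with gene ends was -0.197 (SD 0.112, negative on 18 of 19). Wider zones lay farther from the nearest breakpoint (rho 0.232, SD 0.112, positive on 19 of 19 chromosomes). A wide zone cannot have a close neighbour without overlap, and only 88 neighbouring pairs overlapped. Part of this relation may therefore be built into the list, which was not tested. For the left and right arms of a zone, rho was 0.0179 (SD 0.0756, positive on 10 of 19). These 4 relations are across zones of 1 library, which are not independent replicates, so no p-value was given.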

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

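The share of zones with a gene end kept its direction and stayed outside the placements in all 7 alternatives run. The highest over the lowest chromosome density was 1.71, and 1.66 and 1.69 in 2 alternatives; the 4 relations across zones kept their sign in 3 alternatives each. Keeping only zones at least as wide as the median left 1429 zones of median 138 kb, by construction, and leaving out zones at the 100 kb limit gave 106 kb. With zones less than 10 kb apart merged, the median distance minus placements turned from 12.2 to -91.6 kb. The difference in coefficient of variation turned from -0.0744 to 0.0244. Merging joined more zones in the placements (2457 intervals left) than in the list (2756), where it joined only zones that overlap. The median difference passed the placements with wide zones (65.5 kb) and with placements within 5 Mb windows (28.2 kb). The excess of zone bases in gene bodies, 4.62 percentage points, was 4.07 to 6.03 in 5 alternatives that kept zone bases. With the breakpoint in their place it turned to -12.0, and to -9.79 with breakpoint and all genes, -11.0 with breakpoint and wide zones, -11.9 with breakpoint and no zones at the limit, and -6.36 for the point midway between the edges, since these take the centre of the zone alone. Lists below the random range fell from 4 to 2 with runs of neighbours, and lists above from 4 to 2 with wide zones. Histone enzymes turned to -0.709 points with wide zones and -2.56 with gene midpoints, and the cause was not tested. Histone genes turned to 2.77 with length-matched lists, whose mean was 16.35%, against 38.6% for unmatched lists. Those lists were drawn from a pool that held the receptor genes. Over single lists and alternatives, 82 results were the same, 7 stronger, 13 weaker and 3 reversed; of the named gene distances, 34 moved and 53 stayed the same with wide zones. No paired analysis was possible because only 1 library was analysed. Not run were alternatives by score, which the list does not hold, by genome sequence or strand, and by full chromosome length; leaving out sex chromosomes changes nothing, since all zones are autosomal. Depth is unknown, so weak zones missed by the calling cannot be counted. Alternatives with 5 Mb windows, gene midpoints, length-matched lists, the midway point, the breakpoint with other zones or genes, joined overlaps and the 100 kb limit were chosen after the data were seen.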

Other observations

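The gene families, other kinds of genes, zone-free stretches, gene-free intervals and both tests against placements within 5 Mb windows were chosen after the data were seen, the last once the spacing result was known. Gene families outside the fixed lists, defined by shared symbol stems with at least 25 members, also differed in nearness to zones. Of 60 stems, 10 lay above and 8 below the random range both with single random genes and with runs of neighbours, where chance would give 3 outside with single genes. Families above the range included Rab small GTPases (40 of 65 genes within 20 kb, 61.5%), Polr subunits of RNA polymerases (19 of 28, 67.9%), Rbm RNA-binding proteins (22 of 34, 64.7%), Snx sorting nexins (19 of 29, 65.5%), Usp deubiquitinases (30 of 50, 60.0%) and Eif translation initiation factors (28 of 53, 52.8%). Below the range, no gene of 53 Krt keratins or 56 Krtap keratin-associated proteins lay within 20 kb of a zone (0 in both), nor of 28 Defa defensins (0). Of 38 Tas taste receptors 2 were near, of 33 Clec lectins 3, of 99 Cyp cytochromes P450 19 (19.2%), and of 42 Col genes, mostly collagens, 8 (19.05%). Among other kinds of genes, 179 of 386 tRNA genes (46.4%) lay within 20 kb of a zone, against 17.4% in rotations (6.74 to 31.3%), 359 of 1136 miRNA genes (31.6%, against 13.6 to 25.5%) and 3289 of 12322 lncRNA genes (26.7%, against 18.6 to 20.4%). For snoRNA genes the share of 21.7% was within the rotations (12.8 to 24.6%). Pseudogenes lay just above them, with 1692 of 8797 near (19.2%, against 16.8 to 18.8%); rotations do not keep regional gene density.

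The longest stretches without a zone differed in gene content. On chromosome 7, 8.27 Mb from 6324001 to 14592000 held no zone and 113 protein-coding genes, 53 of them vomeronasal and 8 olfactory receptor genes. The same stretch held Lig1, Zfp551 and Vmn1r67, each the member of its list farthest from a zone, and the imprinted genes Peg3 and Zim1. On chromosome 2, 8.08 Mb from 94028001 to 102107000 held 10 genes, among them Rag1 and Rag2, which encode the recombinase of lymphocyte receptor genes, and Lrrc4c. On chromosome 5, 7.24 Mb from 53583001 to 60827000 held 4 genes, one of them Pcdh7, and on chromosome 14, 6.70 Mb from 78572001 to 85267000 held 14, among them Pcdh8 and Pcdh17.

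Zones might hold gene ends simply because they lie in gene-rich regions. Zones shifted by 200 kb to 1 Mb, which stay in their region, held a gene end in 59.8% of cases (58.2 to 61.5%), above the 52.6% of rotations but below the listed 84.2%, and 0 of 1000 shifts reached it. Regional gene density therefore does not account for the whole excess. No biological explanation was tested, and transcription of the genes near zones stays open.

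Breakpoints lay in gene bodies in 29.2% of zones, and the same shifts gave 45.7% (43.9 to 47.5%), with 0 of 1000 as low. These shifts lay above the rotations (41.1%), so the surrounding region raised this share. Regional gene density could therefore not have given the low share, and the test speaks for no other cause. Nearness to a gene end could lower the share. Among zones that hold a gene end, 30.3% of breakpoints lay in gene bodies. Of shifted zones that hold one it was 54.4% (52.2 to 56.5%), again with 0 of 1000 as low. Holding an end somewhere in the zone does not match its distance from the breakpoint. Listed breakpoints had 0.331 ends per 10 kb, against 0.175 in rotations, so nearness to a gene end stays open. For the 2009 breakpoints between genes, the gene-free interval around the breakpoint had a median of 76.5 kb, against 447.1 kb (397.4 to 504.3 kb) in rotations, which do not keep regional gene density. A candidate explanation is that zones sit between nearby genes; the smoothing and edge rules behind the list, and transcription, stay open as untested.

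Breakpoints were spaced more evenly than independent placement gives, and few of them were close together. Placements that keep the number of breakpoints in each 5 Mb window had a coefficient of variation of 1.04 (1.01 to 1.07). This lay above the listed 0.930, and 0 of 1000 were as low. Keeping regional density raised the variation over placement on the whole chromosome (mean 1.005). Regional differences in zone density could therefore not have produced a lower value, so the test decides nothing about the even spacing. Among distances above 200 kb, the coefficient of variation of the excess over 200 kb was 1.04, within placements on the whole chromosome (0.965 to 1.04) and in 5 Mb windows (0.997 to 1.07). In simulated lists without pairs closer than 150 kb, a stronger scarcity than listed, this value lay above the window placements in 40 of 40 runs, so a value within them leaves open whether scarcity of close breakpoints accounts for the whole pattern. Whether close zones are rare in the cells or were joined when zones were called cannot be separated with 1 list either, and no biological explanation was tested. No gap between zones that do not overlap was shorter than 23 kb, and 62 of the 88 overlapping pairs shared both edges. Because the calling rules are not given, these values do not settle the question.

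A further hypothesis was that zone width follows the length of the gene-free interval around the breakpoint. Over all breakpoints between genes together, it was not borne out. Spearman's rho across the breakpoints between genes was -0.0714, below the rotations (mean -0.00147, -0.0487 to 0.0455), so wider zones lay, if anything, in shorter gaps. Arms stop at 100 kb, and zones with no gene end within 100 kb of the breakpoint were narrow (median 89 kb). Such zones in long gaps can lower rho whatever holds in short ones. The test therefore does not decide whether width follows the gap between nearby genes.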
